A study of Mus musculus with 12 samples.

How the data were processed

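RNA of splenic B cells from control (B1-8hi with floxed Sub1, no Cre) and knockout mice (the same alleles with Mb1-Cre), resting or stimulated for 72 h, was amplified with amino allyl nucleotides, labelled with Cy3 and hybridised to 12 Agilent mouse 8x60K arrays per the labels. Groups and replicate numbers came from the sample labels, and slides from the array identifiers in the files. The values used are background-subtracted processed Cy3 signal intensities on a linear scale, which the authors obtained per the file headers with Agilent Feature Extraction 10.7.3.1, while their processing note names version 9.1. The deposited series matrix holds the same intensities rounded (largest relative difference 0.497%), not normalized between arrays. Each array held 62,976 spots, of which 3671 were controls and 59,305 were not.

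Spots called outliers by the scanner software were set to missing. The log2 of each intensity was taken relative to the array's 75th percentile over non-control spots, and spots of one probe were averaged. Probes well above background on all 3 arrays of at least 1 group were kept. Probes were named through the transcript accession in the array annotation and a table of RefSeq genes of the mouse GRCm38.p6 build, which named 26,413 of 55,681 non-control probes. The brightest probe stood for a gene and the unnamed probes were kept as features of their own, giving 22,981 features, 12,295 of them named genes and 10,686 unnamed. The array annotation refers to an older genome build, so no coordinates were used from it. Of 2806 genes with several probes, those with a called change and a probe of the other sign numbered 23 in the stimulated knockout comparison, 241 and 76 for stimulation in control and knockout cells, 1 for the interaction and none in the resting comparison.

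Changes were tested with limma 3.58.1 in R 4.3.3 (files read with the data.table package, version 1.17.8), with lmFit and eBayes on all 12 arrays, 4 group means and 8 residual degrees of freedom (prior degrees of freedom 2.55). The contrasts were, the knockout effect in resting and in stimulated cells, stimulation in control and in knockout cells, and their interaction. P-values were adjusted by Benjamini-Hochberg over all features of a contrast, with a threshold of 0.05. Every gene-level adjusted p in the text is limma's. A fold change is given as at least so many fold where the dimmer group lay below detection, with the bound taken at the background. Gene lists were tested with camera at the preset correlation of 0.01, with an estimated correlation and fry as alternatives, after 330 missing values had been filled with the group mean. "Adjusted over the list alone" means a Benjamini-Hochberg adjustment within the members of one list.

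The gene lists, the comparisons, most alternative settings and the rule for naming genes were written before the data were examined. Of 27 lists with 394 members, 26 had a tested member, and none of the 12 immunoglobulin constant region genes was named on the array, so that list was not tested. The rule names Sub1 and Cd79a, and the 8 genes with the largest increases and the 8 with the largest decreases among called genes whose groups did not overlap (6 and 6 for stimulation). It also names up to 4 called members per list and comparison, or up to 2 members with the smallest p where none was called, and all 12 study partner transcription factors. One gene that the rule names is not reported here. Lists of abundant macrophage transcripts and of interferon gamma and type I interferon targets were written later, before their tests were run, and the genes named from them were chosen after their values were seen, as were Dock2's second probe and the sex-linked genes outside the tested ones.

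The labels do not say whether same-numbered samples share an animal. Deviations of same-numbered arrays from their group means correlated in all 3 pairs of the stimulated knockout comparison (0.35, 0.33 and 0.48) and of stimulation in control cells (0.42, 0.43 and 0.51), so these comparisons were also fitted with the replicate number as a block. Replicates 1 and 2 lay on slide 1 and replicate 3 on slide 2, so within-slide changes are given.

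Alternatives covered the replicate number or slide as a block, a fit on 2 groups only, quantile normalization, median scaling, normexp background correction (offset 50, on median signals because the files used here hold no mean signals), the series matrix, no filter, a filter on all 12 arrays, every probe on its own, eBayes with trend and robust settings, array weights, a 2-fold limit and leaving out each array. Alternatives added after seeing the data were a percentile over the 12,977 spots detected on all arrays, the same with a filter on those probes, leaving out both arrays of control replicate 1, and slide 1 only. The strength of the response was the ratio of the median changes of the 200 genes with the largest mean change over both genotypes.

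The pipeline was tested on simulated data with 22,981 genes and the observed spread, with 50 genes changed at each of 1.5, 2, 4 and 8-fold. The share recovered at 2, 4 and 8-fold was 12%, 58% and 72% for the resting knockout comparison, 18%, 66% and 82% for the stimulated one, 8%, 62% and 78% for stimulation in control cells, 22%, 58% and 64% in knockout cells, and 2%, 32% and 60% for the interaction, and 0% at 1.5-fold in each. False calls numbered 4, 5, 6, 4 and 4. Camera called between 0 and 3 of 100 unchanged lists at p under 0.05, and a simulated response ratio of 0.8 was recovered as 0.793. Genes and arrays were simulated independently, so this does not test camera on correlated lists or false calls where same-numbered arrays deviate together. Each simulation changed 200 genes, against 6397 and 3692 features called for stimulation in control and knockout cells. The shares recovered therefore do not carry over to these 2 comparisons. In the real data the estimated correlation within a list reached 0.75 (mitosis). Well above background signal covered 41.8% to 64.1% of spots in control resting arrays, 24.3% to 60.1% in control stimulated, 40.5% to 76.6% in knockout resting and 42.6% to 76.8% in knockout stimulated arrays.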

Results

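Gene expression was measured in splenic B cells of mice in a design with 2 genotypes and 2 states. The knockout cells carried a conditional deletion of Sub1 per the labels. Sub1 encodes PC4, a transcriptional coactivator and chromatin protein that binds single-stranded DNA. The floxed Sub1 alleles were targeted by Mb1-Cre, a recombinase knocked into the Cd79a locus and active from early B cell development. Control mice carried the floxed alleles without Cre. Each knockout comparison therefore also sets Cre and its insertion in Cd79a against their absence. Effects of Sub1 loss, of Cre and of lower Cd79a cannot be told apart in this design. Both genotypes carried B1-8hi, a knock-in heavy chain gene whose antibodies bind the hapten NP. Cells were taken either resting or after 72 h of culture with IL-2, IL-4, IL-5, CD40 ligand and NP-ficoll. Each of the 4 groups held 3 replicates, hybridised to 12 one-colour arrays on 2 slides, with replicates 1 and 2 of all groups on slide 1 and replicate 3 of all groups on slide 2. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. Only control replicate 1 carried Ddx3y and Eif2s3y signal and no Xist, so the control samples did not all come from the same animal. The title names PC4 in B cell differentiation together with IKAROS and IRF4, and the design text asks how PC4 acts in B cells. Between 24.3% (control stimulated replicate 2) and 76.8% (knockout stimulated replicate 3) of spots were well above background. No spot was saturated, and the number of arrays limits the precision. Levels are log2 intensities relative to each array's 75th percentile, as mean ± SD with n = 3, changes are log2 differences with SE, and p-values are limma adjusted p over 22,981 features unless stated.

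Sub1, the targeted gene, was lower in stimulated knockout than in stimulated control cells. Its brighter probe read 8.05 ± 0.22 in control and 6.84 ± 0.11 in knockout stimulated cells (n = 3 each), a change of -1.21 (SE 0.19, 2.31-fold, adjusted p = 0.0114). Within slide 1 the change was -1.20 and within slide 2 it was -1.23. In resting cells the levels were 6.03 ± 0.04 and 5.65 ± 0.24, and the change of -0.38 (SE 0.19) did not pass the test (adjusted p = 0.268; slides -0.46 and -0.23). The labels do not give the floxed exons, so it is open whether this probe lies in the deleted part, and a probe outside it checks nothing. A dimmer Sub1 probe, well above background on 10 arrays, gave -0.86 in resting and 0.09 in stimulated cells. The Sub1 call in stimulated cells ended without knockout stimulated replicate 1 or replicate 2, with changes of -1.15 and -1.23, and without both arrays of control replicate 1, at -1.13. Cd79a, the signalling chain of the B cell receptor whose locus carries the Cre insertion, read 4.56 ± 0.26 in control resting, 3.01 ± 0.03 in knockout resting, 3.67 ± 0.29 in control stimulated and 2.58 ± 0.36 in knockout stimulated cells. It was lower by -1.10 (SE 0.24) in stimulated knockout cells (adjusted p = 0.0343; slides -0.98 and -1.32). In resting cells the change of -1.54 (SE 0.24) missed the threshold (adjusted p = 0.0948; slides -1.68 and -1.27).

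**Figure D1:**
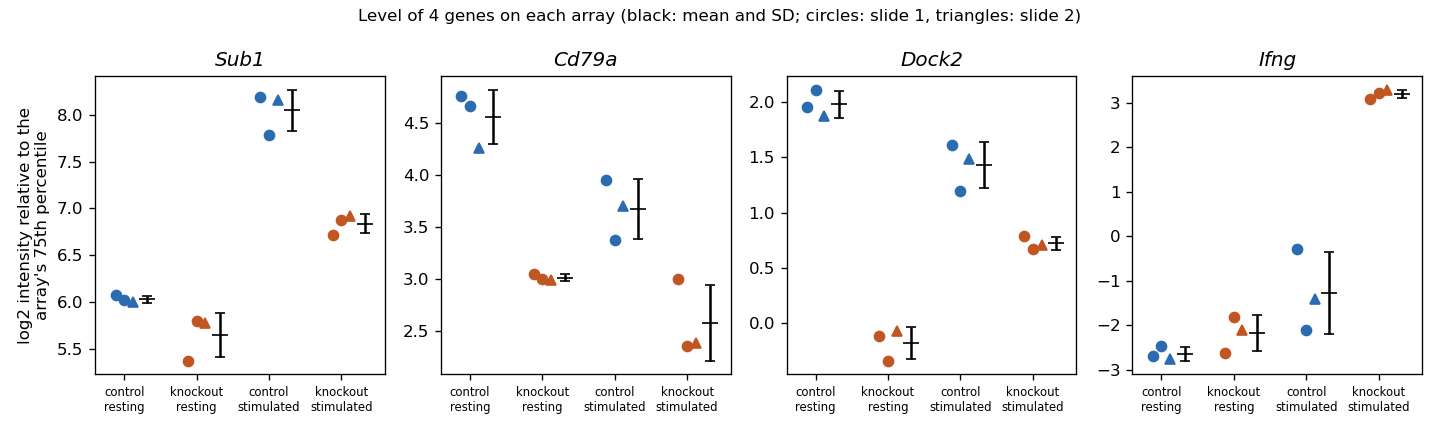
Each point is one array's log2 intensity relative to its 75th percentile for Sub1, Cd79a, Dock2 and Ifng, by group, with slide 1 as circles and slide 2 as triangles. Black marks give the mean and SD of 3 arrays. Sub1 averaged 8.05 in control and 6.84 in knockout stimulated cells, and the 3 Ifng values of stimulated knockout cells, between 3.09 and 3.29, lay above every other array.

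Without stimulation, 3 genes passed the threshold between knockout and control B cell preparations. Dock2, a guanine nucleotide exchange factor for Rac that lymphocytes need to migrate, was 4.46-fold lower in the knockout, with levels of 1.98 ± 0.12 in control and -0.18 ± 0.14 in knockout cells (change -2.16, SE 0.18, adjusted p = 0.00326; slides -2.26 and -1.94). Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1, was higher by 1.82 (SE 0.22, adjusted p = 0.0417; slides 1.89 and 1.69). Tbxas1, the thromboxane synthase gene, was higher by 1.78 (SE 0.20, adjusted p = 0.04; slides 1.96 and 1.42). The calls of Hmox1 and Tbxas1 ended in 14 and 13 of 24 other settings and that of Dock2 in 5. All 3 resting knockout arrays lay beyond all 3 control arrays for each of these genes. Myeloid markers stood higher in the same arrays, with a median of 1.50, so the increases of Hmox1 and Tbxas1 need not lie in B cells.

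Gene lists moved in both directions in resting knockout cells. Of 13 early B genes Igll1, Rag1, Rag2, Dntt, Il7r and Erg were not above background and were not tested, and the other 7 had a median of 0.69, with 2 higher when adjusted over the list alone. Lef1 and Sox4, transcription factors of lymphoid progenitors, had changes of 1.49 (adjusted p = 0.0965) and 1.34 (adjusted p = 0.183). T cell markers stood higher in the same arrays, with a median of 0.88, so these increases need not lie in B cells. The camera adjusted p of these 7 was 0.000218, and 0.0341 with an estimated correlation, and the median reached 1.05 with a single array left out. Mature B cell identity genes had a median of -0.55, with negative changes in all 20 members and 3 lower when adjusted over the list alone (camera adjusted p = 0.000186, and adjusted p = 0.575 with an estimated correlation; slides -0.66 and -0.34). Among them Cr2, the complement receptor of follicular and marginal zone cells, had a change of -1.76 (SE 0.38, adjusted p = 0.158). Marginal zone B genes had a median of -0.57 over 11 members, 3 of them lower when adjusted over the list alone, with changes of -1.39 in Dtx1 (adjusted p = 0.14) and -1.06 in Hes5 (adjusted p = 0.158). The list's camera adjusted p was 0.0106, and 0.575 with an estimated correlation. Dtx1 and Hes5 are targets of Notch signalling. B-1 and innate-like B genes had a median of 0.53 over 8 members, with 2 higher when adjusted over the list alone (camera adjusted p = 0.0106, and adjusted p = 0.139 with an estimated correlation). Bhlhe41, a transcription factor of B-1a cells, had a change of 1.30 (adjusted p = 0.206). The plasma cell program had a median of 0.36 over 15 members, with 6 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0106, and adjusted p = 0.65 with an estimated correlation). Jchain, which joins immunoglobulin polymers, had a change of 1.44 (adjusted p = 0.206). Leaving out single arrays moved the plasma cell median between 0.09 and 0.54 and ended its call without knockout resting replicate 2 (adjusted p = 0.124), and moved the B-1 median between 0.27 and 0.63 and ended its call without knockout resting replicate 1 (adjusted p = 0.0531).

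Markers of other cells stood higher in the same resting knockout arrays. Myeloid markers had a median of 1.50 over 13 members, with 7 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.08e-05, and adjusted p = 0.0283 with an estimated correlation; slides 1.63 and 1.44). The complement genes C1qa and C1qb, made by macrophages, had changes of 1.85 (adjusted p = 0.153) and 1.50 (adjusted p = 0.0954). Erythroid markers had a median of 2.14 over 4 members (camera adjusted p = 0.00749), T cell markers 0.88 over 9 (camera adjusted p = 0.00749) and NK cell markers 0.63 over 8 (camera adjusted p = 0.0116). None of the last 3 calls held with an estimated correlation (adjusted p = 0.556, 0.556 and 0.575), and the erythroid median was 0.92 on slide 1 and 5.04 on slide 2. With single arrays left out the erythroid median ranged from 1.09 to 2.83, the T cell median from 0.48 to 1.11 and the NK median from 0.43 to 0.87. The erythroid call ended without control resting replicate 3, the T cell call without knockout resting replicate 3 and the NK call without either of these. Oxidative phosphorylation genes had a median of -0.33 over 15 members and MYC and ribosome biogenesis genes -0.28 over 18, with camera adjusted p = 0.0115 and 0.0449. With an estimated correlation both had adjusted p = 0.714, and the oxidative phosphorylation median turned to 0.03 with quantile normalization. The MYC median was -0.03 there, and its call ended without control resting replicate 1 or 2 or knockout resting replicate 3. The median change of all features was -0.21 in this comparison, and the medians of these lists relative to it were -0.33 for mature B genes, 0.57 for plasma cell genes and -0.07 for MYC genes.

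The study partner transcription factors gave no call in resting cells (median -0.34 over 12, camera adjusted p = 0.177). Ikzf1 and Ikzf3 had changes of -0.34 (adjusted p = 0.32) and -0.63 (adjusted p = 0.24), Irf4 of -0.55 (adjusted p = 0.237), Prdm1 of 0.36 (adjusted p = 0.382), Batf of -0.36, Bach2 of -0.22, Pax5 of -0.37, Bcl6 of -0.34, Irf8 of -0.14, Spi1 of -0.13 and Spib of -0.07, with adjusted p up to 0.802. Class switch and germinal centre genes had negative changes in all 13 members without a call (median -0.35, camera adjusted p = 0.093). The unfolded protein response (median -0.12), cholesterol synthesis (-0.28), glycolysis and hypoxia (-0.36), mitosis (-0.25), DNA replication (-0.35), chromatin compaction (-0.33), interferon response (0.02), activation (-0.07), p53 (-0.15), immediate early (-0.28), autophagy (-0.23) and platelet lists (0.48) had camera adjusted p from 0.0871 to 0.988. Single arrays left out moved many of these medians by over 1.5 times, that of mitosis between -0.48 and -0.15 and that of interferon response between -0.11 and 0.15.

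The resting comparison called 2 genes higher and 1 lower by limma, against 4534 features with an unadjusted p under 0.05. With the percentile taken over probes detected on all arrays 51 genes passed, 45 higher and 6 lower, and with median scaling 3 passed, all lower. No gene passed without control resting replicate 1, control resting replicate 2 or knockout resting replicate 2, and 12 passed without knockout resting replicate 3. Without control stimulated replicate 2 the count was 6, and it was 1 without any one of control stimulated replicates 1 and 3 and knockout stimulated replicates 1, 2 and 3.

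After stimulation, 796 features passed the threshold between the genotypes, 277 higher and 519 lower in the knockout, or 34.8% higher. By limma 5082 features had an unadjusted p under 0.05, against 4534 in resting cells, so the 2 states differ less by this count than by calls. With the replicate number as a block 1865 passed, of which 795 were shared with the 796. Genes of antibody-secreting cells were lower. The plasma cell program fell with a median of -1.40 over 15 members, 10 of them lower and 12 lower and 1 higher when adjusted over the list alone (camera adjusted p = 5.52e-09; slides -1.39 and -1.32). Tnfrsf17, the plasma cell survival receptor BCMA, changed by -3.61 (SE 0.66, adjusted p = 0.0192) and Jchain by -2.45 (SE 0.44, adjusted p = 0.0179). Prdm1, which encodes the plasma cell regulator BLIMP-1, fell from 3.73 ± 0.22 to 2.31 ± 0.06, a change of -1.42 (SE 0.26, adjusted p = 0.0197). Its call ended in 7 of 23 other settings, among them quantile normalization and the removal of any one knockout stimulated array. The unfolded protein response and secretion list fell with a median of -1.16 over 22 members, 14 of them lower and 20 lower when adjusted over the list alone (camera adjusted p = 1.1e-14; slides -1.09 and -1.28). Its examples Creld2 and Manf, chaperone-associated proteins of the endoplasmic reticulum, changed by -1.68 (SE 0.29, adjusted p = 0.0156) and -1.63 (SE 0.21, adjusted p = 0.0057). With an estimated correlation both lists had adjusted p = 0.0994. Myeloid markers stood higher in the same arrays, with a median of 2.19.

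NK cell markers had a median of 1.97 in these same cells. Cholesterol synthesis genes fell with a median of -1.16 over 18 members, 11 of them lower and 17 lower when adjusted over the list alone (camera adjusted p = 3.69e-14; slides -1.16 and -0.96). Fdps changed by -1.77 (SE 0.27, adjusted p = 0.0114) and Sqle, squalene epoxidase, by -1.36 (SE 0.26, adjusted p = 0.0213). Glycolysis and hypoxia genes fell with a median of -1.11 over 16 members, 9 of them lower and 14 lower when adjusted over the list alone (camera adjusted p = 9.36e-11; slides -1.44 and -0.58). Vegfa changed by -2.09 (SE 0.33, adjusted p = 0.0121) and Hk2, hexokinase 2, by -1.58 (SE 0.29, adjusted p = 0.0193). With an estimated correlation both lists had adjusted p = 0.0994. MYC and ribosome biogenesis genes had a median of -0.55 over 18 members, with 2 lower, the polyamine enzyme genes Srm at -1.32 (adjusted p = 0.0322) and Odc1 at -1.08 (adjusted p = 0.042), and 8 lower when adjusted over the list alone (camera adjusted p = 7.96e-06, and adjusted p = 0.3 with an estimated correlation). DNA replication genes had a median of -0.49 over 17 members, 1 of them lower when adjusted over the list alone (camera adjusted p = 0.000251). Oxidative phosphorylation genes had a median of -0.44 over 15, mitosis genes -0.42 over 16 and chromatin compaction genes -0.34 over 14, with no member past the test (camera adjusted p = 3.73e-05, 0.0021 and 0.00806). With an estimated correlation these last 4 had adjusted p = 0.345, 0.345, 0.528 and 0.345. Quantile normalization turned the oxidative phosphorylation median to 0.01 and the chromatin compaction median to 0.05, and the chromatin compaction call ended without knockout stimulated replicate 3 (adjusted p = 0.0815). Quantile normalization also brought the medians of mitosis to -0.03, of DNA replication to -0.09 and of MYC genes to -0.18. It ended 4 of the 14 list calls of this comparison and added 3. Single arrays left out moved the medians of DNA replication between -0.64 and -0.32, oxidative phosphorylation between -0.57 and -0.28, mitosis between -0.55 and -0.25 and chromatin compaction between -0.44 and -0.20.

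The 8 largest decreases, with Tnfrsf17 and Jchain among them, were led by Mgarp. The arginine transporter gene Slc7a3 changed by -3.38 (SE 0.36, adjusted p = 0.00206), Chac1, which degrades glutathione, by -2.76 (SE 0.30, adjusted p = 0.00243) and asparagine synthetase, Asns, by -2.43 (SE 0.42, adjusted p = 0.0154). Mgarp changed by -3.79 (adjusted p = 0.0192) and Hid1, a gene of dense core vesicle biogenesis, by -2.87 (adjusted p = 0.00635). Slc16a3, the lactate transporter MCT4, changed by -2.82 (adjusted p = 0.0372), with -3.95 on slide 1 and -0.56 on slide 2. Mgarp was well above background on 1 of 3 knockout stimulated arrays and Slc7a3 on 2 of 3, so their changes rest partly on dim spots.

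Of the 12 study partner transcription factors, Sub1, Irf4 and Prdm1 were lower in stimulated knockout cells. Irf4, a factor for class switching and plasma cell differentiation, fell from 5.69 ± 0.42 to 4.25 ± 0.15, a change of -1.44 (SE 0.22, adjusted p = 0.0114; slides -1.43 and -1.47). Its call ended in the same 4 settings as that of Sub1, with no filter, without knockout stimulated replicate 1 or 2 and without both arrays of control replicate 1. When adjusted over the list alone 5 were higher and 3 lower. Bach2, which represses Prdm1, had a change of 0.91 (adjusted p = 0.075), Irf8 0.70 (adjusted p = 0.0932), Spib 0.62 (adjusted p = 0.109), Pax5 0.86 (adjusted p = 0.178) and Bcl6 0.73 (adjusted p = 0.182). With the replicate number as a block Bach2 and Irf8 passed. Ikzf1, the IKAROS gene, had a change of 0.13 (SE 0.21, adjusted p = 0.719) and Ikzf3 of 0.40 (adjusted p = 0.388). Batf and Spi1 had changes of -0.39 (adjusted p = 0.236) and -0.29 (adjusted p = 0.475). The list's median was 0.26 and its mean -0.03, with camera adjusted p = 0.935.

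Interferon genes were higher in stimulated knockout cells. Ifng, the interferon gamma gene, was higher by 4.47 (SE 0.39, adjusted p = 0.00152; slides 4.36 and 4.69). It was well above background on 2 of 3 control stimulated arrays, so its change rests partly on a dim spot. The interferon response list rose with a median of 0.84 over 18 members, 3 of them higher and 9 higher when adjusted over the list alone (camera adjusted p = 3.38e-06, and adjusted p = 0.0994 with an estimated correlation; slides 0.71 and 1.06). Gbp2, a guanylate-binding protein gene, changed by 2.56 (SE 0.29, adjusted p = 0.0026), and Ifit2 was at least 1.5-fold higher (adjusted p = 0.0127). NK cell markers, with a median of 1.97, stood higher in the same arrays. The 7 tested early B genes had a median of 0.59, with 1 higher, Lef1 at 1.39 (SE 0.24, adjusted p = 0.0168), and 4 higher when adjusted over the list alone (camera adjusted p = 0.000974, and adjusted p = 0.0902 with an estimated correlation). Their median reached 0.92 with a single array left out. T cell markers stood higher in these arrays too, with a median of 0.97, so the increase of Lef1 need not lie in B cells. Tbx21, the T-bet gene, was the only member of the B-1 list past the test, at 1.86 (SE 0.33, adjusted p = 0.0182), and that list was not called (median 0.49, camera adjusted p = 0.0849). Egr1, an immediate early gene, changed by 1.82 (adjusted p = 0.00985) in a list that was not called (median 0.18 over 12, camera adjusted p = 0.156).

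Markers of other cells were higher in the same stimulated knockout arrays. Myeloid markers rose with a median of 2.19 over 13 members, 5 of them higher and 8 higher when adjusted over the list alone (camera adjusted p = 2.31e-07, and adjusted p = 0.0174 with an estimated correlation; slides 2.22 and 1.54). C1qc changed by 4.01 (SE 0.45, adjusted p = 0.00261), and C1qa was at least 3.85-fold higher (adjusted p = 0.00206). NK cell markers rose with a median of 1.97 over 8 members, 5 of them higher over all features and over the list alone (camera adjusted p = 7.5e-07, and adjusted p = 0.0994 with an estimated correlation; slides 1.56 and 2.34). Among them the granzyme genes Gzmb and Gzma changed by 3.14 (adjusted p = 0.00554) and 3.1 (adjusted p = 0.0346). T cell markers rose with a median of 0.97 over 9 members, 2 of them higher, Cd3g at 2.24 (adjusted p = 0.0481) and Bcl11b at 1.54 (adjusted p = 0.0464), and 4 higher when adjusted over the list alone (camera adjusted p = 0.00127, and adjusted p = 0.225 with an estimated correlation). With the replicate number as a block Cd3g no longer passed, and its call ended in 18 and that of Bcl11b in 17 of 23 other settings. The 8 largest increases, with Ifng and C1qc among them, were led by Ear2 and Ccl6. Ear2, an eosinophil ribonuclease gene, changed by 5.87 (SE 0.80, adjusted p = 0.00635; slides 7.11 and 3.38), the chemokine gene Ccl6 by 5.25 (adjusted p = 0.00194), and Tgm2, transglutaminase 2, by 4.50 (adjusted p = 0.00152). Rnase2a was at least 7.61-fold higher (adjusted p = 0.0185). Haemoglobin alpha changed by 4.64 as Hba-a2 (SE 1.08, adjusted p = 0.0438) and was at least 9.87-fold higher as Hba-a1 (adjusted p = 0.0437). The erythroid list had a median of 1.17 over 4 members (camera adjusted p = 0.1) and the platelet list 0.26 over 8 (camera adjusted p = 0.456), in which Itgb3 changed by 1.28 (adjusted p = 0.0483). Single arrays left out moved the erythroid median between 0.19 and 1.42 and the platelet median between -0.19 and 0.83, with adjusted p down to 0.027 and 0.0331.

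The remaining lists were not called between stimulated genotypes. Mature B cell identity genes had a median of 0.04 over 20 members, with Ccr7 higher by 1.00 (adjusted p = 0.0315) and Fcer2a, the CD23 gene, at -1.01 (adjusted p = 0.0421), and camera adjusted p = 0.587. Marginal zone B genes had a median of 0.06 (camera adjusted p = 0.27), class switch and germinal centre genes -0.26 (camera adjusted p = 0.435), p53 targets -0.12 (camera adjusted p = 0.587) and autophagy genes -0.24 (camera adjusted p = 0.176). B cell activation markers had a median of 0.18 (camera adjusted p = 0.422), with Slamf1 lower (adjusted p = 0.0246) and not well above background on any knockout stimulated array. Single arrays left out moved the mature B median between -0.14 and 0.18, the marginal zone median between -0.05 and 0.32 and the class switch median between -0.48 and -0.13. The 2 tested sex-linked genes, Xist and Uty, had a median of 1.53 (camera adjusted p = 0.187), and both arrays of control replicate 1 differed from all other arrays in Xist.

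**Figure D2:**
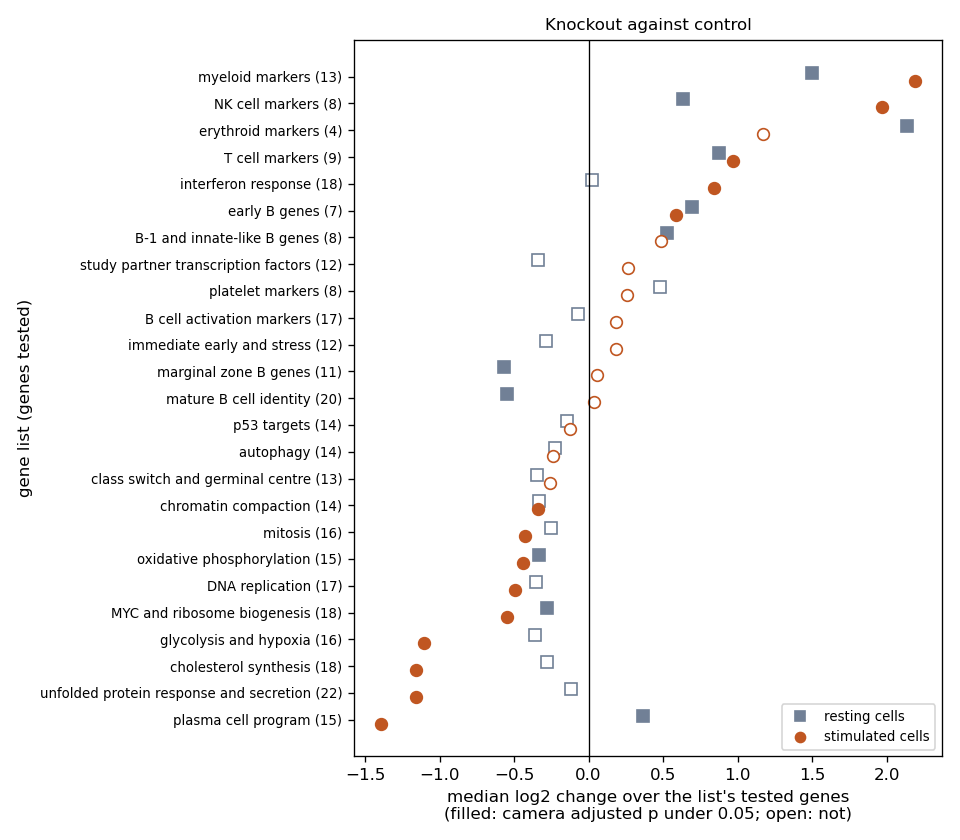
Median log2 change of each gene list between knockout and control, in resting (grey squares) and stimulated cells (orange circles), with the number of genes tested after each name; filled symbols have a camera adjusted p under 0.05. In stimulated cells the plasma cell program stood lowest at -1.40 and myeloid markers highest at 2.19. With quantile normalization the stimulated medians of oxidative phosphorylation and chromatin compaction lay above 0.

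The direction split of the stimulated comparison moved with the scaling, the filter and the arrays used. Quantile normalization called 546, with 57.1% higher, median scaling 678, with 11.9% higher, and a percentile over probes detected on all arrays 2349, with 84.2% higher and 640 shared with the 796. The filter on all 12 arrays called 118 higher and 1380 lower, and a fit on the 2 groups alone 61 higher and 32 lower. No named gene called here changed sign under any of these scalings. With slide as a block 1309 passed, on slide 1 alone 6 passed, and without both arrays of control replicate 1, the only arrays with Ddx3y and Eif2s3y signal, 38 passed, 27 higher and 11 lower. Single arrays moved the count as well. It was 48, with 36 higher, without knockout stimulated replicate 2, 115 without replicate 1 and 278 without replicate 3 of that group, 153 without control stimulated replicate 1 and 1457 without control stimulated replicate 2. It was 391, 434 and 478 without control resting replicates 1, 2 and 3, and 390 and 429 without knockout resting replicates 1 and 2. Of 24 other settings 16 ended the call of Fcer2a, 15 those of Hba-a2, Slc16a3 and Itgb3, 14 those of Srm and Cd79a, 13 those of Ccr7 and Odc1 and 12 that of Gzma. Of 23 settings 16 ended the call of Hba-a1, 12 that of Slamf1 and 7 those of Tbx21, Lef1 and Ifit2. The calls of Creld2, Hk2 and Sqle ended in 7 of 24, those of Jchain, Asns and Fdps in 5 of 24, those of Tnfrsf17, Mgarp, Vegfa and Rnase2a in 5 of 23 and that of Egr1 in 4 of 23.

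Stimulation changed 6397 features in control cells, 3386 higher and 3011 lower, which is 52.9% higher. Mitosis genes led the increases. All 16 tested mitosis genes rose (median 3.63, camera adjusted p = 2.17e-17), with Birc5 at 3.99 (SE 0.29, adjusted p = 1e-05) and Cdk1 at 3.97 (SE 0.35, adjusted p = 2.45e-05). Of 17 DNA replication genes 15 rose (median 2.31, camera adjusted p = 1.92e-13), with the ribonucleotide reductase gene Rrm2 at 4.09 and Cdc6 at 3.64. Chromatin compaction genes rose in 12 of 14 (median 1.62, camera adjusted p = 2.24e-08), with the linker histone gene H1f5 at 3.50 (adjusted p = 7.4e-05). The plasma cell program rose in 11 and fell in 1 of 15 (median 2.37, camera adjusted p = 6.09e-09), with Tnfrsf17 at 4.85 (SE 0.66, adjusted p = 0.000326), and the unfolded protein response list rose in 18 of 22 (median 1.96, camera adjusted p = 1.87e-12), with Creld2 at 3.50 and Manf at 3.36. Cholesterol synthesis genes rose in 17 of 18 (median 2.09, camera adjusted p = 1.24e-13), with Fdps at 2.99 and Sqle at 2.93. Glycolysis and hypoxia genes rose in 14 of 16 (median 1.61, camera adjusted p = 3.57e-09), with Vegfa at least 24.2-fold higher, oxidative phosphorylation genes in 14 of 15 (median 0.78, camera adjusted p = 3.36e-06) and MYC and ribosome biogenesis genes in 10 of 18, with 1 lower (median 0.81, camera adjusted p = 0.000152). None of these 9 lists was called with an estimated correlation, with adjusted p from 0.0871 to 0.295.

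Resting B cell genes fell with stimulation. Mature B cell identity genes fell in 17 of 20 (median -1.73, camera adjusted p = 3.06e-12), led by Cr2 at -7.86 (SE 0.38, adjusted p = 2.08e-06), with Cd55 at -3.01. Marginal zone B genes fell in 9 and rose in 1 of 11 (median -2.28, camera adjusted p = 6.24e-06), with S1pr3 at -3.89. Immediate early and stress genes fell in 9 of 12 (median -2.15, camera adjusted p = 4.91e-08), with Egr1 at -3.79 and Fos at least 10.6-fold lower. Interferon response genes fell in 12 and rose in 1 of 18 (median -1.96, camera adjusted p = 3.85e-07), with Oasl1 at -5.11, Ifit3 at least 9.72-fold lower and Zbp1 higher by 2.24. Myeloid markers fell in 7 of 13 (median -2.04, camera adjusted p = 6.02e-06), platelet markers in 4 of 8 (median -1.58, camera adjusted p = 0.0135) and erythroid markers in 2 of 4 (median -2.87, camera adjusted p = 0.0205). The myeloid list kept its call with an estimated correlation (adjusted p = 0.0455), and the other 6 had adjusted p from 0.0871 to 0.295. The erythroid call ended without control stimulated replicate 2 or 3. Among the transcription factors Prdm1 rose by 4.64 (SE 0.26, adjusted p = 3.89e-06), Irf4 by 2.28 (SE 0.22, adjusted p = 4.47e-05), Sub1 by 2.01 (SE 0.19, adjusted p = 3.42e-05) and Batf by 1.23. The dimmer Sub1 probe gave the other sign, -0.98 in control and -0.02 in knockout cells. Bcl6, Bach2, Pax5, Irf8, Spib, Ikzf3 and Ikzf1 fell, with changes of -2.27, -2.18, -1.90, -1.55, -1.48, -1 and -0.85 and adjusted p up to 0.0158. The Ikzf3 call ended in 7 of 23 and the Ikzf1 call in 3 of 24 other settings. Spi1 had a change of -0.58 (adjusted p = 0.0935) and passed with the replicate block.

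The largest increases were those of the cytokine-induced regulator genes Cish at 7.46 (SE 0.33) and Socs2 at 6.71 (SE 0.35), of the IL-2 receptor gene Il2ra at 6.29 (SE 0.25) and of Nfil3 at 6.14 (SE 0.25), with adjusted p between 7.49e-07 and 2.61e-06. Drc1, a ciliary dynein regulator gene, was at least 89.1-fold higher and Gzmb at least 40.7-fold higher. The largest decreases after Cr2 included Hba-a1, at least 55.1-fold lower, Hba-a2 at -7.08, the ICOS ligand gene Icosl at -5.53 and Rasgef1b at -5.24. B-1 genes (median 1.37, 5 higher and 2 lower of 8, camera adjusted p = 0.039), p53 targets (median 0.44, 6 higher of 14, camera adjusted p = 0.0362) and NK cell markers (median 0.58, 2 higher of 8, camera adjusted p = 0.0377) were called higher. These 3 had adjusted p = 0.106, 0.36 and 0.36 with an estimated correlation. The NK call was lost with the replicate block (adjusted p = 0.0586) and without any one of 5 arrays (median 0.31 to 0.80, adjusted p up to 0.12), and the B-1 and p53 calls without any one of 2 arrays each. Class switch and germinal centre genes were not called (6 higher and 4 lower of 13, median 0.57, mean -0.08, camera adjusted p = 0.511), nor were activation markers (5 higher and 8 lower of 17, median -0.53, mean 0.08, camera adjusted p = 0.215), early B genes (median 0.01, camera adjusted p = 0.51), the transcription factors (median -0.93, camera adjusted p = 0.218), autophagy genes (median 0.19, camera adjusted p = 0.7) or T cell markers (median -0.42, mean 0.03, camera adjusted p = 0.498). Quantile normalization called 6595, with 41.8% higher, and the percentile over probes detected on all arrays 8519, with 29.2% higher. Median scaling called 3346, and without both arrays of control replicate 1 the count was 3411.

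In knockout cells stimulation changed 3692 features, 2498 higher and 1194 lower, or 67.7% higher. The same 19 lists were called in the same directions. All 16 mitosis genes rose (median 3.29), as did 15 of 17 DNA replication genes (median 2.16), 11 of 14 chromatin compaction genes (median 1.59), 14 of 18 cholesterol synthesis genes (median 1.23), 8 of 16 glycolysis and hypoxia genes (median 0.97) and 12 of 22 unfolded protein response genes (median 0.90). The plasma cell program rose in 8 and fell in 2 of 15 (median 1.08). Mature B cell identity genes fell in 11 of 20 (median -0.87), marginal zone genes in 6 of 11 (median -1.39) and interferon response genes in 9 of 18, with 2 higher (median -1.28). Prdm1 rose by 2.85 (SE 0.26, adjusted p = 8.27e-05), Irf4 by 1.38 (SE 0.22, adjusted p = 0.00208) and Sub1 by 1.19 (SE 0.19, adjusted p = 0.00179). NK cell markers rose in 5 of 8 (median 1.95), myeloid markers fell in 6 of 13 (median -1.17) and erythroid markers in 4 of 4 (median -4.10). Camera adjusted p lay between 5.56e-22 and 0.0283, and with an estimated correlation the myeloid list alone was called (adjusted p = 0.0387), the next lowest being 0.0832. The plasma cell call ended without knockout stimulated replicate 3 (adjusted p = 0.0598) and the p53 call without replicate 1 of that group. Quantile normalization called 4554, with 51.6% higher, and the percentile over probes detected on all arrays 4942, with 36.3% higher. The count was 2313, 1817, 2169 and 2302 without knockout stimulated replicate 1 or 2 and knockout resting replicate 1 or 2.

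**Figure D3:**
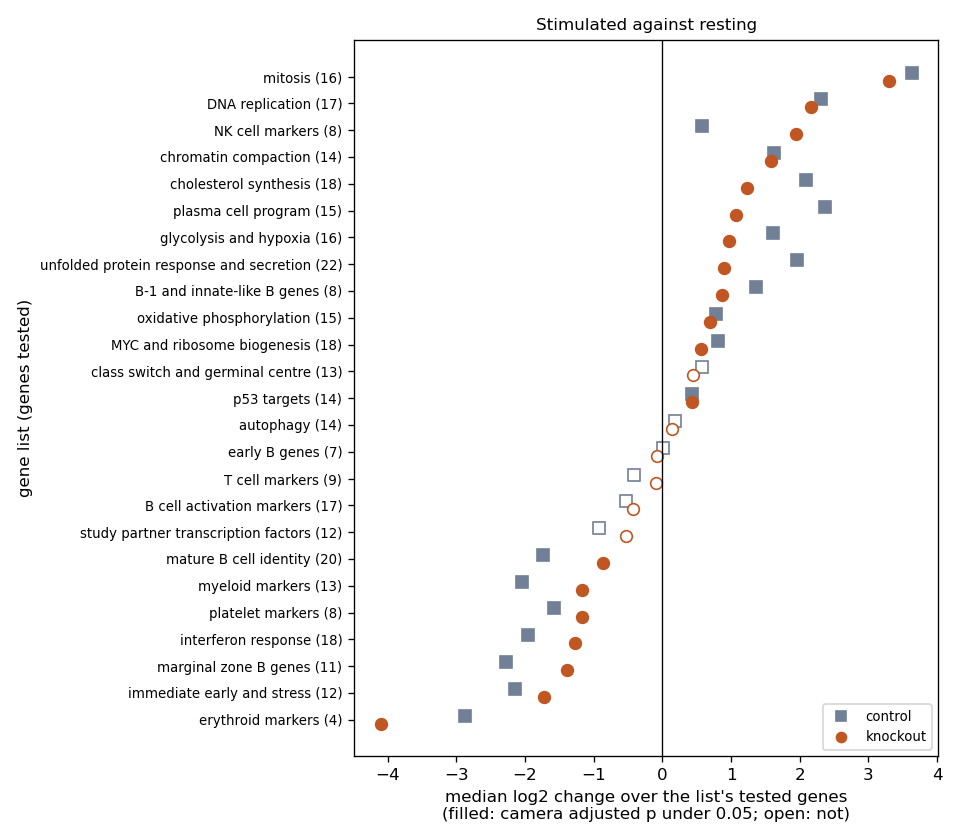
Median log2 change of each gene list between stimulated and resting cells, in control (grey squares) and knockout cells (orange circles), with the number of genes tested after each name; filled symbols have a camera adjusted p under 0.05. Mitosis genes stood at 3.63 in control and 3.29 in knockout cells, and the plasma cell program at 2.37 and 1.08.

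The interaction asked whether stimulation acted differently in the 2 genotypes, and 33 features passed, 12 higher and 21 lower. Higher values mean a larger increase or smaller decrease in knockout cells. Ifng had the largest positive interaction, 4.01 (SE 0.55, adjusted p = 0.0333; slides 4 and 4.02), and the interferon-inducible genes Tgtp2, Irgm2 and Irf1 had 2.95, 2.08 and 1.79 (adjusted p = 0.0408, 0.0459 and 0.0427). Afp, Serpinb9, Zmat1 and Jade2 had 3.25, 2.42, 1.98 and 1.93 (adjusted p up to 0.0459). The lowest values were those of Hid1 at -4.44 (SE 0.55, adjusted p = 0.0247), Slc7a3 at -3.93 (adjusted p = 0.0282), Jchain at -3.89 (adjusted p = 0.0497) and Plcd1 at -3.37 (adjusted p = 0.0282), followed by Bhlha15, the secretory cell factor MIST1, at -3.32, Ckb at -3.06, Chac1 at -2.91 and Nupr1 at -2.89 (adjusted p up to 0.0427). Each of these 16 calls ended in 10 to 17 of 23 or 24 other settings. Prdm1 and Irf4 had -1.79 (adjusted p = 0.102) and -0.90 (adjusted p = 0.322).

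By lists, the plasma cell program had a median interaction of -1.34 (camera adjusted p = 4.12e-16, 12 of 15 lower when adjusted over the list alone), the unfolded protein response list -1.03 (camera adjusted p = 5.82e-17, 14 of 22), cholesterol synthesis -0.90 (camera adjusted p = 2.2e-12, 8 of 18) and glycolysis and hypoxia -0.67 (camera adjusted p = 1.21e-08, 2 of 16). Interferon response genes had 0.97 (camera adjusted p = 0.000125, 7 of 18 higher when adjusted over the list alone), mature B cell identity genes 0.67 (camera adjusted p = 4.85e-05, 1 of 20, slides 0.89 and 0.19) and marginal zone genes 0.60 (camera adjusted p = 0.000342, 4 of 11, slides 1.25 and 0.06). Other-cell markers moved here too, NK at 1.37 (camera adjusted p = 0.00133) and myeloid at 0.87 (camera adjusted p = 0.0253; slides 1.11 and -0.10). DNA replication (-0.23), MYC and ribosome biogenesis (-0.21) and immediate early genes (0.49) were called by camera with adjusted p = 0.036, 0.0155 and 0.0155. The marginal zone median reached 0.93 with a single array left out. The calls of DNA replication, MYC and immediate early genes ended without any one of 6, 4 and 3 arrays, with medians from -0.34 to -0.06, -0.29 to -0.04 and 0.29 to 0.76, and the myeloid call without control stimulated replicate 1 or knockout stimulated replicate 2. No list was called with an estimated correlation, where the lowest adjusted p was 0.18. The count of 33 was 0 without knockout stimulated replicate 1 or 2, knockout resting replicate 1 or 2 or any control resting replicate, 12, 4 and 1 without knockout stimulated replicate 3, knockout resting replicate 3 and control stimulated replicate 1, and 125 without control stimulated replicate 2. By limma 2445 features had an unadjusted p under 0.05, and 317 passed with the percentile over probes detected on all arrays, 55.8% higher against 36.4% of the 33.

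Across the 200 most induced genes, chosen on the mean of both genotypes, the median response was 3.77 in control and 3.15 in knockout cells, a ratio of 0.837, and 166 of 200 responded less in the knockout (camera p = 4.31e-20, p = 0.0712 with an estimated correlation). With quantile normalization the ratio was 0.985. Across the 200 most repressed genes the medians were -3.19 and -3.05, a ratio of 0.955 (camera p = 0.151, p = 0.54 with an estimated correlation).

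The knockout effects in resting and stimulated cells share no array. Of the genes called in both states 1 was higher in both, Tbxas1 (0.0241 would be shared by independent lists), and none was lower in both. At an unadjusted p under 0.01, 581 features were higher in resting and 834 in stimulated knockout cells, with 118 shared against 21.1 for independent lists. Among the 118 were the macrophage genes Adgre1, C1qa, C1qb, C1qc, Mpeg1 and Spic, so this overlap may partly reflect other cells. Of 492 and 1168 lower features 39 were shared, against 25. Across the 22,981 features the log2 changes correlated with Pearson r = 0.474 and Spearman rho = 0.442, though features are not independent replicates. Same-numbered control arrays of both states deviated together, so numbers for independent lists and a correlation of 0 are not proper values for no shared effect.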

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

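In the patterns weighed here, the tests of a lower B cell share, of dilution and of a uniformly weaker response were chosen only after the result was seen, and the others were fixed before their values were computed.

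The interaction singled out genes and lists whose response to stimulation differed between the genotypes. Genes with a larger value in knockout cells were Ifng (4.01), Afp (3.25), Tgtp2 (2.95), Serpinb9 (2.42), Irgm2 (2.08), Zmat1 (1.98), Jade2 (1.93) and Irf1 (1.79). Genes with a smaller value were Hid1 (-4.44), Slc7a3 (-3.93), Jchain (-3.89), Plcd1 (-3.37), Bhlha15 (-3.32), Ckb (-3.06), Chac1 (-2.91) and Nupr1 (-2.89). Lists with a negative median were the plasma cell program (-1.34), the unfolded protein response (-1.03), cholesterol synthesis (-0.90), glycolysis and hypoxia (-0.67), DNA replication (-0.23) and MYC and ribosome biogenesis (-0.21). Lists with a positive median were NK cell markers (1.37), interferon response (0.97), myeloid markers (0.87), mature B cell identity (0.67), marginal zone B genes (0.60) and immediate early genes (0.49). The response ratio of the most induced genes was 0.837, and 0.985 with quantile normalization. With an estimated correlation the camera p of the main ratio was 0.0712. None of these lists was called with an estimated correlation, where the lowest camera adjusted p was 0.18. When 100 of the 200 possible groupings of the arrays were tested, 1 of them, the real one, called as many as 33 genes, and the next highest called 9. These groupings did not keep same-numbered arrays together, and the count was 0 without any one of 7 arrays, so the test cannot tell whether chance is excluded.

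Markers of other cell types stood higher in the stimulated knockout cultures. A lower share of B cells that raised all other cells alike would move the myeloid, NK, T, erythroid and platelet lists by the same amount. Their 42 members differed between lists (permutation p = 0.0168). The permutation treats genes as independent, while the estimated correlation within lists reached 0.73 (erythroid). Gzmb, Gzma and Thy1 also rose with stimulation in control cultures, so such markers need not track a cell share. The test therefore cannot tell. To weigh scaling or background of dim probes, the myeloid and NK medians were ranked, and lay at percentile 100 of 10000 random lists matched on level. These 2 lists were picked for being high in this comparison, so the ranking cannot tell. Both medians kept their sign in the other scalings, at 1.38 and 1.51 with normexp background correction. The random lists did not carry the correlation within the marker lists. Macrophages in the cultures would bring their abundant transcripts, and 12 of these, written down before the test, had a median of 0.55 (95% bootstrap bounds 0.23 and 1.92, comparison value 1.10, taken from the myeloid median), so the test cannot tell. Fcer1g, Tyrobp, Aif1 and Apoe were higher by 2.48, 2.26, 1.93 and 1.80, while Ctsd, Ctsb, Lamp1, Cst3 and Ftl1 had changes between -0.37 and 0.37. The labels give no sort or gate that would have removed macrophages.

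Plasma cell, unfolded protein response and cholesterol genes stood lower in the same cultures. Dilution of B cell RNA by other cells would lower mature B cell genes as much. Their median of 0.04 lay 1.21 above the pooled median of -1.18 (permutation p = 1e-05, the smallest possible, 75 genes). Mature B cell genes did not fall as a list here, though their median was -0.52 with median scaling. They are no fixed measure of dilution, since stimulation lowered them by -1.73 in control and by -0.87 in knockout cells. The pooled lists were also picked because they were low. How far dilution lowered the pooled lists therefore stays open. The p itself is too small, because the permutation treats genes as independent, and estimated correlations within these lists reached 0.45. For scaling of bright probes, the highest of the 3 list medians lay at percentile 0 of the matched random lists. Since the 3 lists were picked for being low, this ranking cannot tell whether scaling lowered them. Their medians kept their sign in the other scalings. These random lists likewise lacked the correlation within the real lists. A uniformly weaker response would give these lists the same response ratio as mitosis and DNA replication genes. Among genes that rose more than 2-fold in control cells, the median ratio was 0.929 for mitosis and DNA replication genes. It was 0.522 for the pooled lists, a difference of 0.407 (permutation p = 1e-05, 77 genes). The pooled lists were picked for being low in stimulated knockout cells, and the permutation treats genes as independent. No conclusion is therefore drawn on a uniformly weaker response. A smaller share of cells that became plasma cells and a lower output per cell are both left open by bulk RNA.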

How the results depend on the processing

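Each group held 3 arrays, with 24.3% to 76.8% of spots well above background. Settings chosen before the files were seen moved counts as follows, and the cause was not tested. For the knockout effect in resting cells (main count 3) the replicate block called 41, slide as a block 12, a fit on 2 groups 0, quantile normalization 34, normexp 90, no filter 0, a filter on all 12 arrays 60, trend and robust eBayes 1.1e+02 (43 higher and 64 lower) and array weights 122. For the knockout effect in stimulated cells (796) the replicate block called 1865, slide as a block 1309, 2 groups 93, no filter 56, the filter on all 12 arrays 1498 and trend and robust 1536. For stimulation in control cells (6397) median scaling called 3346 and no filter 3883, and in knockout cells (3692) 1683 and 1606. For the interaction (33) slide as a block called 81, quantile normalization 81, median scaling 10, normexp 123, no filter 0, the filter on all arrays 266, trend and robust 335 and array weights 100. Added after seeing the data, the percentile over probes detected on all arrays called 51, 2349 and 317 for the knockout effect in resting and stimulated cells and the interaction, and the same with a filter on those probes 101, 1771 and 873. Without both arrays of control replicate 1 the counts were 0, 38 and 0, and 3411 for stimulation in control cells, and on slide 1 only 0, 6 and 0, and 3546 and 1486 for stimulation in control and knockout cells. All these counts are limma's.

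The replicate block gave 33 for the interaction, 19 of them shared, and Ifng, Afp, Irgm2, Zmat1, Jade2, Chac1 and Nupr1 lost their interaction calls. For the knockout effect in resting cells and stimulation in knockout cells same-numbered arrays did not all correlate (-0.11, 0.20 and 0.39; 0.0029, 0.15 and 0.39), so the numbers are only shared there. Beside the counts, Cd3g in stimulated cells and the NK list under stimulation, the block ended no call, and beside Bach2 and Irf8 in stimulated cells and Spi1 under stimulation it added none, among the genes and lists given in the text for the stimulated knockout comparison or stimulation in control cells.

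Leaving out one array gave 0 to 12 calls for the knockout effect in resting cells, 48 to 1457 in stimulated cells, 4387 to 6382 for stimulation in control and 1817 to 4135 in knockout cells, and 0 to 125 for the interaction. Sub1 ranged from -0.46 to -0.25 in resting and -1.34 to -1.13 in stimulated cells, Cd79a from -1.69 to -1.45 and -1.30 to -0.96. Response ratios ranged from 0.807 to 0.907 for induced and 0.874 to 0.975 for repressed genes, and shared knockout calls from 0 to 5.

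Cd79a in resting cells passed with the replicate block (-1.54), quantile normalization (-1.27), normexp (-1.44), the filter on all arrays (-1.54), trend and robust (-1.54), array weights (-1.53) and the added percentile (-1.19). In stimulated cells it no longer passed with quantile normalization (-0.72), no filter (-1.10), array weights (-1.10) or without control replicate 1 (-0.96), nor with any one array left out except control resting replicate 3 and control stimulated replicate 2. Sub1 in stimulated cells no longer passed with no filter (-1.21) or without control replicate 1 (-1.13), and its dimmer probe was reversed (0.0934). The repressed ratio passed by camera with 400 genes (0.880) and normexp (0.925), and without any one of 5 arrays, but in neither of the first settings with an estimated correlation (p = 0.2 and 0.363). Shared knockout calls were 20 with the replicate block, 13 with quantile normalization and 157 at an unadjusted p under 0.01. With quantile normalization the resting median of oxidative phosphorylation genes was reversed (0.0301), and that of MYC genes kept its sign (-0.0298) while the direction of camera turned. Of the other results under settings chosen beforehand 7815 kept direction and side of the threshold, 150 gained a call, 716 lost one and 2 reversed, and under added ones 744, 34 and 82.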

Other observations

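For the patterns here, the test of a sequence variant in Dock2 was chosen only after the result was seen, and the others were fixed before their values were computed.

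Stimulation also changed genes outside the programs described above. Thy1, a surface protein of T cells, rose by 5.70 in control cells (SE 0.54, limma adjusted p = 3.58e-05), while Cd8a was at least 1.46-fold lower, a call that ended in 5 of 23 other settings. Gzma, a granzyme gene, rose by 4.16 (limma adjusted p = 0.00103). Among B-1 genes Zbtb32 and Spn rose by 4.52 and 2.61 and Tbx21 and Cd5 changed by -1.96 and -0.77, and the Cd5 call ended in 16 of 23 other settings. Of the p53 targets Phlda3 and Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 2.94 and 1.81. Class switch and germinal centre genes split, with Exo1 and Msh6, which act in mismatch repair, higher by 3.34 and 1.25, and Rgs13 and Gcsam, genes of germinal centre B cells, at least 4.55-fold and at least 2.19-fold lower. Of 14 autophagy genes 2 rose, Bnip3 by 2.01 and Gabarapl1 by 0.97, and 2 fell, Atg7 at -0.83 and Atg12 at -0.68 (limma adjusted p up to 0.0455). The call of Bnip3 ended in 14 of 24, that of Atg12 in 13 of 24, that of Atg7 in 5 of 23 and that of Gabarapl1 in 2 of 24 other settings. The neutrophil gene S100a9 changed by -4.99, with -6.77 on slide 1 and -1.43 on slide 2, and its call ended in 4 of 23 other settings.

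Both arrays of control replicate 1 carried signal of the Y-linked genes Ddx3y and Eif2s3y and no Xist. Xist read -4.42 and -3.91 in the resting and stimulated array, not well above background, with Ddx3y at 2.32 and 1.62 and Eif2s3y at 2.62 and 3.03. On the other 10 arrays Xist read between 0.09 and 1.77, Ddx3y at most -2.09 and Eif2s3y at most -2.25. Uty, another Y-linked gene, did not follow this pattern and was well above background on 3 of 3 resting and 2 of 3 stimulated knockout arrays. The labels give no sex.

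Dock2 was lower in resting knockout cells by both of its probes, at -2.16 and -2.75. The second probe was well above background on 8 of 12 arrays, so its changes rest partly on dim spots. A probe over a sequence variant would lose as much signal in both states, but the change in stimulated cells was -0.71 and -0.69, and the smaller ratio of a probe's interaction to its SE was 4.24, which argues against a probe effect alone. A wider chromosome region of other origin carried with the alleles might change neighbours as well, and the 40 nearest neighbours lay at percentile 94.5 of other windows, so the test cannot tell.

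As a hypothesis, the interferon genes of stimulated knockout cultures could reflect interferon gamma signalling, since Ifng was higher by 4.47. Interferon gamma targets had a median of 1.05 over 17 genes, 6 of them higher, among them Gbp4 (1.85), Gbp5 (1.69) and Irgm1 (1.53), while Ciita and Psmb8 had changes of -0.23 and -0.29. Type I interferon targets had a median of 0.73 over 12 genes. The difference of 0.32 had a permutation p of 0.205, so the test cannot tell the interferon types apart, and it does not show which cells made Ifng.

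For the comparisons within one state or genotype, 10 splits of 3 against 3 arrays exist, too few for a share under 0.05. As many genes as in the real grouping were called in 2 splits for the knockout effect in resting cells and in 1, the real one, for the knockout effect in stimulated cells, for stimulation in control cells and for stimulation in knockout cells.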
